A study of Homo sapiens with 18 samples.

How the data were processed

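Polyadenylated RNA ends were measured in 18 libraries of MCF-10A cells, a human mammary epithelial line that is not tumorigenic. Per the labels' protocols, total RNA was extracted with Trizol and sequenced on an Illumina HiSeq instrument by 3'READS, a method that captures and sequences the 3' ends of polyadenylated transcripts. Per the submitters' processing notes, the reads were aligned with Bowtie and the build was hg19. The Bowtie version and any filter on reads are not given in the sources used here.

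Each deposited file held 50835 rows, 1 per transcript model, and its values were signal: per the file headers, the authors summed read starts over a window of 400 nt past the stop codon and over the coding span, and listed the 20 most used positions of each window. The deposited signal was scaled by 1 factor per library, since the low values of every library were whole multiples of a single step. The step ranged from 0.1866 in the library with oncostatin M and IFN-Y to 2.6544 in the untreated library. Dividing by the step recovered whole reads, with a tolerance of 0.1 reads, for at least 99.81% of low values and at least 97.09% of all values in every library. The authors' reason for the scaling is not given in the sources used here.

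From these files, 39173 rows of coding transcripts were used, 11477 noncoding rows were left out, and 185 coding rows on chromosome Y were left out. The remaining rows formed 22414 distinct windows and 19177 gene symbols. For the 2858 symbols with more than 1 window, the window with the highest mean was kept. A further 408 symbols shared a window with another symbol, and 26 symbols were written as dates in the deposited files and kept that way. Reads more than 400 nt past the stop codon were not counted, and 68.5% of the symbols had a longer annotated 3' UTR, so a low value in such a gene does not show low expression. Windows of neighbouring genes on opposite strands were checked for shared reads: 13 of 6768 listed positions were identical in 136 convergent pairs. Window reads per library ranged from 2279724 to 12596352, with a median of 5185586, which sets the precision of low genes.

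No condition had a second library. The labels give 1 library per combination of 6 additions, and the libraries were treated as an incomplete factorial in which libraries that share an addition replicate that addition. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, part of which may be technical. The model held 6 additive terms and left 11 residual degrees of freedom, which carry both library noise and departures from additivity. Because the deposited values are scaled signal and not read counts, the main test was limma-trend (limma 3.58.1, R 4.3.3, robust) on log2(normalised RPM + 1), with TMM factors and the filterByExpr rule of edgeR 4.0.16, which kept 6278 genes. Fold changes are on that scale, which understates the change of low genes. TMM factors ranged from 0.680 to 1.46. P-values were adjusted by Benjamini-Hochberg over the 6278 genes for each addition, with a threshold of 0.05. The quasi-likelihood test of edgeR, the tool planned for the main test on counts, was run on the recovered reads as an alternative. That use was chosen after the data were seen. EdgeR called 173 genes for oncostatin M and 1 for IFN-Y, against 217 and 4 with limma-trend. Product terms were tested 1 at a time for 8 pairs of additions. Mean 3' end positions were tested with limma in 1063 genes with at least 50 reads in every library.

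Before the data were examined, 26 gene lists, most alternatives and the rule for naming genes were fixed. The tests were also fixed then, but not all were kept. The plan named edgeR on counts as the main gene test, with limma-trend for normalised values. It also set another log2 scale for the lists and matched pairs. Limma-trend took the place of edgeR, and log2(normalised RPM + 1) that of the planned scale. Lists were tested with camera of limma at a preset correlation of 0.01, on log2(normalised RPM + 1), with adjustment over 120 list tests. The same scale served the matched pairs. The 6 lists with fewer than 5 measured members were described only. The rule took, for oncostatin M and IFN-Y, the 10 largest increases and the 10 largest decreases, and 5 of each for the other additions, among genes past the threshold with a mean log2 value of at least 3 and the same direction in every matched pair. It also took up to 4 members of each list in order of adjusted p, and the receptors of the added ligands in full. RARRES3, ST13 and COTL1 fell outside the rule and were named after their values were seen. Matched pairs are libraries that differ by 1 addition only.

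The alternatives were other scalings (upper quartile factors, library size only), other tools (DESeq2 1.42.0, limma-voom), other filters, matched pairs as blocks, subsets of the libraries, added terms and the removal of each library in turn. Chosen after seeing the data were edgeR on the recovered reads, pseudocounts of 0.25 and 4, window plus coding-span reads, removal of each library's GC trend by loess with a span of 0.5, the first residual component as a covariate, reads thinned to the smallest library, the libraries without untreated and LIGHT, and, for the gene lists, library size only and the removal of each library. GC content came from GENCODE transcripts of a later build, over 200 nt, for 16859 symbols matched by accession and 382 by symbol, and no coordinates of that build were used.

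The limma step was tested on simulated libraries, in which genes varied independently and had no GC trend. In the gene and product tests, changed genes were drawn only among those with a mean RPM of at least 3 on the log2 scale. The shares recovered and false may therefore be more favourable than in the real libraries. For oncostatin M, run on 5897 genes, it recovered 10% of changed genes at a log2 change of 1, 68% at 2, 98% at 3 and 100% at 4, and 6.76% of its calls were false. For IFN-Y, run on 5775 genes, it recovered 2%, 50%, 86% and 100%, with 3.25% false calls. For LPS, run on 5823 genes, it recovered 0%, 28%, 72% and 88%, with 4.08% false calls. For the product of oncostatin M and IFN-Y, run on 5751 genes, it recovered 0%, 8%, 18% and 60%, with 8.51% false calls. In the simulated list test for oncostatin M, run on 6278 genes, both moved lists and 0 of the others were called. In the simulated position test for LIGHT, run on 1000 genes with a spread of 2 nt, 200 of 200 shifts of 10 nt were recovered and 6 other genes were called. Counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Python 3.11.15 was used for reading the files and drawing.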

Results

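The study asked which genes follow cellular transformation in MCF-10A cells. Its 18 libraries comprised 1 untreated library and 17 libraries of cells given oncostatin M (OSM, a cytokine of the interleukin 6 family), IFN-Y (read here as interferon gamma), TGF-a (a ligand of the EGF receptor), HGF (the ligand of MET), LPS (a bacterial lipopolysaccharide) or LIGHT (a ligand of the tumour necrosis factor family), alone or combined. OSM was present in 10 libraries, IFN-Y in 8, TGF-a in 7, HGF in 6, LPS in 3 and LIGHT in 3. No library held TGF-a alone or HGF alone, so no matched pair for either starts from the untreated library. Window reads ranged from 2279724 in the untreated library to 12596352 in the library with OSM, LPS and LIGHT. The degree of transformation of each condition is not in the labels used here, so no relation with it was computed. Libraries are named by their additions, for example OSM+IFN+HGF. Levels are normalised RPM, window reads scaled to the effective size of the library, in the 400 nt past the stop codon, where the 3' UTR begins, and coordinates are hg19. Where levels have an SD, n is the number of libraries with or without the addition, which also differ in the other additions.

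The comparison of libraries with and without OSM asked which genes followed this cytokine whatever else was added. The largest fitted log2 increases were those of IL1RL1 and IL1R2. IL1RL1, the interleukin 33 receptor (chromosome 2, 102927962 to 102962560), was at 636 ± 461 RPM with OSM (SD, n = 10) and 2.57 ± 2.58 RPM without it (SD, n = 8). IL1R2, a decoy receptor for interleukin 1 on the same chromosome (102608306 to 102644884), was at 312 ± 198 RPM and 3.13 ± 3.44 RPM. TREM1, a receptor best known from myeloid cells (chromosome 6, 41242999 to 41254457), was at 168 ± 63.0 RPM and 3.21 ± 2.50 RPM. S100A8, a calcium-binding subunit of calprotectin (chromosome 1, 153362508 to 153363664), rose from 264 ± 169 RPM to 8165 ± 5148 RPM. The log2 fold changes were 7.57 (SE 0.45) for IL1RL1, 6.50 (SE 0.38) for IL1R2, 5.48 (SE 0.38) for TREM1 and 4.78 (SE 0.43) for S100A8, and the highest limma adjusted p of the 4 was 1.17e-07. Each of these genes was higher in 8 of 8 matched pairs, which the naming rule required. Levels are those of the 1 window kept per gene, so transcript forms that end elsewhere were not counted. The annotated 3' UTRs of IL1RL1 (2668 nt) and TREM1 (923 nt) run past that window. For them a shift of 3' ends cannot be told apart from a change in level.

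Other genes among the 10 largest increases under the naming rule followed. FGL1, a fibrinogen-like secreted protein, rose by 5.25 on the log2 scale, SERPINA1, alpha-1-antitrypsin, by 3.84, and C11orf91 by 3.88. The annotated 3' UTR of SERPINA1 (1702 nt) also runs past the counted window, with the same limit. MTMR11, of the myotubularin family, went from 16.7 ± 9.69 RPM without OSM (SD, n = 8) to 235 ± 76.1 RPM with it (SD, n = 10). MT1F, a metallothionein whose family members are close in sequence, rose by 3.54. HSD17B2, which oxidises estradiol and testosterone (chromosome 16, 82068858 to 82132139), was at 2567 ± 694 RPM with OSM (SD, n = 10) and 435 ± 644 RPM without it (SD, n = 8), a log2 change of 3.36. The untreated library was the exception among those without OSM, with 2019.95 RPM of HSD17B2.

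KRT15 and KRT81 were among the genes that fell. KRT15 (chromosome 17, 39669997 to 39675270), a basal keratin, changed by −4.10 on the log2 scale (SE 0.61), from 544 ± 878 RPM without OSM (SD, n = 8) to 25.1 ± 27.7 RPM with it (SD, n = 10), at a limma adjusted p of 6.09e-04. KRT81, a hair-type keratin with close paralogs (chromosome 12, 52679697 to 52685299), changed by −3.30 (SE 0.44), from 6415 ± 6423 RPM to 546 ± 396 RPM, at a limma adjusted p of 4.60e-05. FBLN1, an extracellular matrix protein, changed by −3.94, and S100A4 by −3.12. SAA1, an acute-phase protein with the near-identical copy SAA2, changed by −3.11, from 2974 ± 1669 RPM to 352 ± 317 RPM. RAMP1 (−2.53), FGFBP1 (−2.44), SNCG (−2.29), ACSL5 (−2.14) and SELENBP1 (−1.99) completed the 10 largest decreases under the naming rule.

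**Figure D1:**
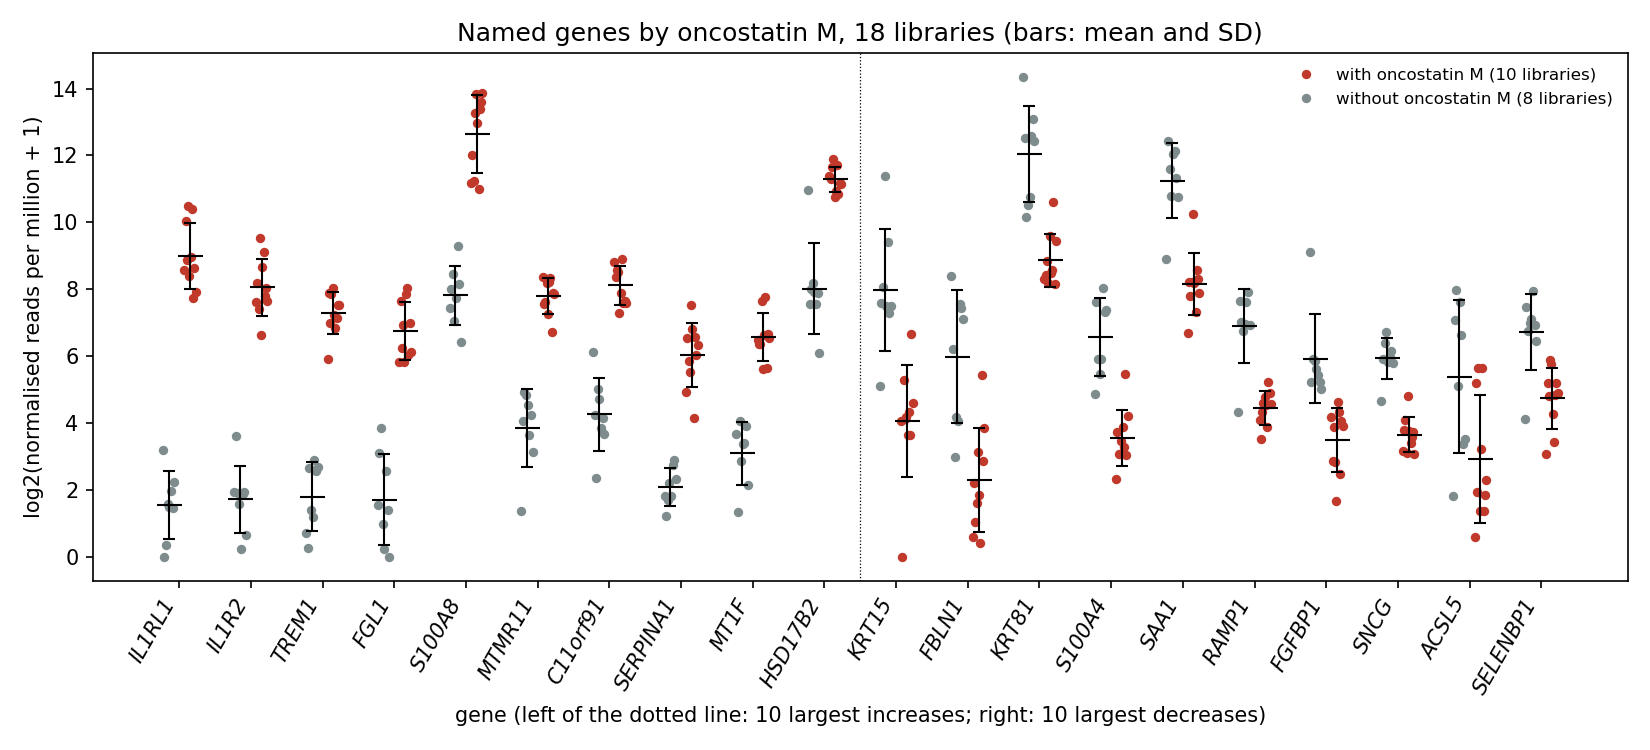
Log2(normalised RPM + 1) of the 10 largest increases and the 10 largest decreases with OSM under the naming rule. Each point is a library (10 with and 8 without OSM), bars are mean and SD, and IL1RL1 has a mean of 636 RPM with OSM and 2.57 RPM without it.

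In all, 217 of 6278 genes (3.46%) passed the limma threshold for OSM, 139 higher and 78 lower, and 149 of them moved the same way in all 8 matched pairs. All 217 changed at least 2-fold, and 29 at least 8-fold. With upper quartile factors 145 genes rose and 79 fell, but with library size only 106 rose and 149 fell. With DESeq2, which changes the test as well as the scaling, 247 rose and 357 fell. The count was 135 without the LIGHT library and 546 without the OSM+TGFa+HGF library.

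**Figure D2:**
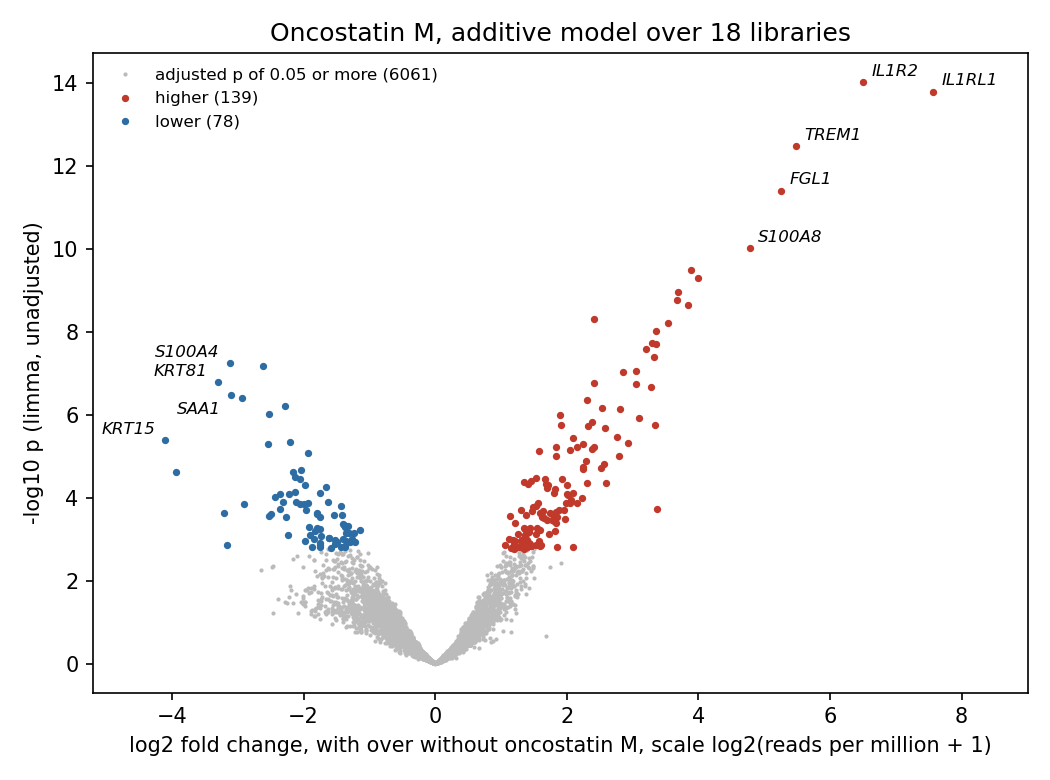
Log2 fold change of each of 6278 genes with OSM (horizontal axis) against −log10 of the unadjusted limma p (vertical axis). The 139 genes that rose are red, the 78 that fell are blue, and IL1RL1 and IL1R2 lie farthest from the rest.

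Among the gene lists fixed beforehand, the squamous differentiation list shifted upward with OSM, though not every member rose. Of 11 measured members, 5 rose and 0 fell over all genes, and adjusted over the list alone 6 rose and 1 fell. S100A8 led the list. S100A12, another calcium-binding protein of the S100 family, was at 11.7 ± 5.72 RPM with OSM (SD, n = 10) and 0.380 ± 0.874 RPM without it (SD, n = 8). SERPINB3, a protease inhibitor with the close paralog SERPINB4, had 743 reads with OSM and 1 read without it, a depth-scaled ratio of 488 (95% interval 87.3 to 19304). S100A9, the partner of S100A8, was at 7514 ± 10072 RPM with OSM and 468 ± 474 RPM without it, and was higher in 7 of 8 pairs, but its call was lost without the untreated library (limma adjusted p = 0.0535). The camera test of limma gave an adjusted p of 5.13e-06 for the list, and adjusted p = 0.00930 with an estimated correlation.

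STAT3 and OSM target genes went both ways: 1 of 13 measured members rose and 1 fell, and adjusted over the list alone 4 rose and 2 fell. SERPINA3, an acute-phase protease inhibitor, rose by 2.30 on the log2 scale, from 95.2 ± 63.4 RPM (SD, n = 8) to 449 ± 188 RPM (SD, n = 10), while SAA1 fell. The camera adjusted p for that list was 0.444. CXCL3, a neutrophil chemokine, rose by 3.68 and was the 1 member that passed among 13 NF-kappa B targets and among 9 secreted inflammatory genes, both over all genes and adjusted over the list alone. Among 8 measured proteases and inhibitors, CTSL, a lysosomal protease, rose by 3.06 and PLAUR, the urokinase receptor, by 2.57, and adjusted over the list alone 2 rose and 1 fell. CA9, a hypoxia-induced carbonic anhydrase, rose by 2.02 and was the 1 member of 22 glycolysis and hypoxia genes that passed, as it was adjusted over the list alone. SERPING1, the C1 inhibitor, rose by 2.85, the 1 member that passed of 15 interferon gamma targets.

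The lists of ATF4 targets and cholesterol genes passed camera downward with OSM, but not with an estimated correlation. Of 14 measured targets of ATF4, a transcription factor of the integrated stress response, 3 fell over all genes and 7 adjusted over the list alone. SLC3A2, a subunit of amino acid transporters, went from 946 ± 357 RPM (SD, n = 8) to 359 ± 107 RPM (SD, n = 10), SLC7A5, its transporter partner, changed by −2.27, and PHGDH, the first enzyme of serine synthesis, by −1.87. The camera adjusted p was 0.0482, with adjusted p = 0.611 with an estimated correlation, and the call was lost on removal of any of 10 single libraries, with adjusted p up to 0.108 without LPS. Of 19 cholesterol genes, INSIG1, a feedback regulator of sterol synthesis, fell by 1.92 over all genes and 3 fell adjusted over the list alone, with a camera adjusted p of 0.00849 and adjusted p = 0.429 with an estimated correlation. The calls of SLC3A2, PHGDH, SLC7A5 and INSIG1 were lost on removal of any of 10, 13, 3 and 7 single libraries, with limma adjusted p reaching 0.114 without LPS, 0.131 without OSM+IFN, 0.125 without LIGHT and 0.138 without LIGHT.

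Of the markers measured, 1 of 12 basal, 0 of 6 luminal, 3 of 4 fibroblast and 1 of 2 leukocyte markers passed for OSM, and the basal and luminal lists did not pass camera (adjusted p = 0.815 and 0.322). KRT5, a basal keratin, changed by −1.14 on the log2 scale, from 1403 ± 501 RPM (SD, n = 8) to 656 ± 237 RPM (SD, n = 10), and was the 1 of 12 basal markers that passed, while adjusted over the list alone 2 rose and 1 fell. Of 6 luminal markers 0 passed limma over all genes and 1 fell adjusted over the list alone, KRT7, with a log2 change of −1.15. Of 4 measured fibroblast markers, DCN rose by 1.69, FAP rose by 1.46 and S100A4 fell by 3.12, with the same counts adjusted over the list alone. CD14, the LPS co-receptor and a monocyte marker, rose from 61.6 ± 10.7 RPM to 259 ± 197 RPM, 1 of 2 measured leukocyte markers. No endothelial marker was measured. OAS1, an interferon-stimulated gene, fell by 1.63, 1 of 14 of its kind, and CLDN7, a claudin, by 1.37, 1 of 11 junction genes, both also adjusted over the list alone. The calls of KRT5, CD14, FAP and CLDN7 were lost on removal of any of 8, 6, 14 and 14 single libraries, with limma adjusted p up to 0.133 without OSM+IFN+HGF for KRT5 and 0.228, 0.148 and 0.155 without LIGHT for the others.

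No member of 9 further lists passed limma over all genes for OSM: 27 proliferation genes, 29 ribosomal protein genes, 12 mesenchymal genes, 12 p53 targets, 9 MAP kinase outputs, 8 stress genes, 6 luminal markers, 2 genes of MHC class I presentation and 1 of class II. Adjusted over the list alone, KRT7 and ERAP2, a peptidase of MHC class I presentation, passed and no other member of these lists did. At an unadjusted p under 0.05, 1077 of all 6278 genes passed for OSM, and edgeR called 173 and limma-voom 232. Mitochondrially encoded genes were not in the rows used here.

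The comparison of libraries with and without IFN-Y asked which genes followed this cytokine. ACSL5, an acyl-CoA synthetase (chromosome 10, 114133916 to 114188138), rose most, from 6.85 ± 9.86 RPM (SD, n = 10) to 103 ± 85.4 RPM (SD, n = 8), a log2 change of 3.69 (SE 0.49) at a limma adjusted p of 5.64e-04. GBP2, an interferon-induced GTPase (chromosome 1, 89571816 to 89591842), rose from 55.8 ± 33.4 RPM to 308 ± 119 RPM, a change of 2.65 (SE 0.47), and the untreated library had 4.72 RPM. SERPING1 (chromosome 11, 57365027 to 57382326) rose by 2.38 (SE 0.44) and RARRES3, a phospholipase family member, by 2.62 (SE 0.49), both at a limma adjusted p of 0.0262. SERPING1 ranged from 23.3 to 65.1 RPM in the 4 libraries with both IFN-Y and OSM and from 2.71 to 7.11 RPM in those with IFN-Y alone or with TGF-a or HGF. The product term of OSM and IFN-Y gave 0 genes in limma, which recovered 8% of simulated products at a log2 size of 2 and 60% at 4, and 72 genes in DESeq2. ACSL5 was higher with IFN-Y in 5 of 5 matched pairs, as were the other 3 genes. The naming rule required this of all but RARRES3. The annotated 3' UTRs of ACSL5 (1022 nt) and GBP2 (2042 nt) run past the counted window, so a shift of their 3' ends cannot be told apart from a change in level.

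**Figure D3:**
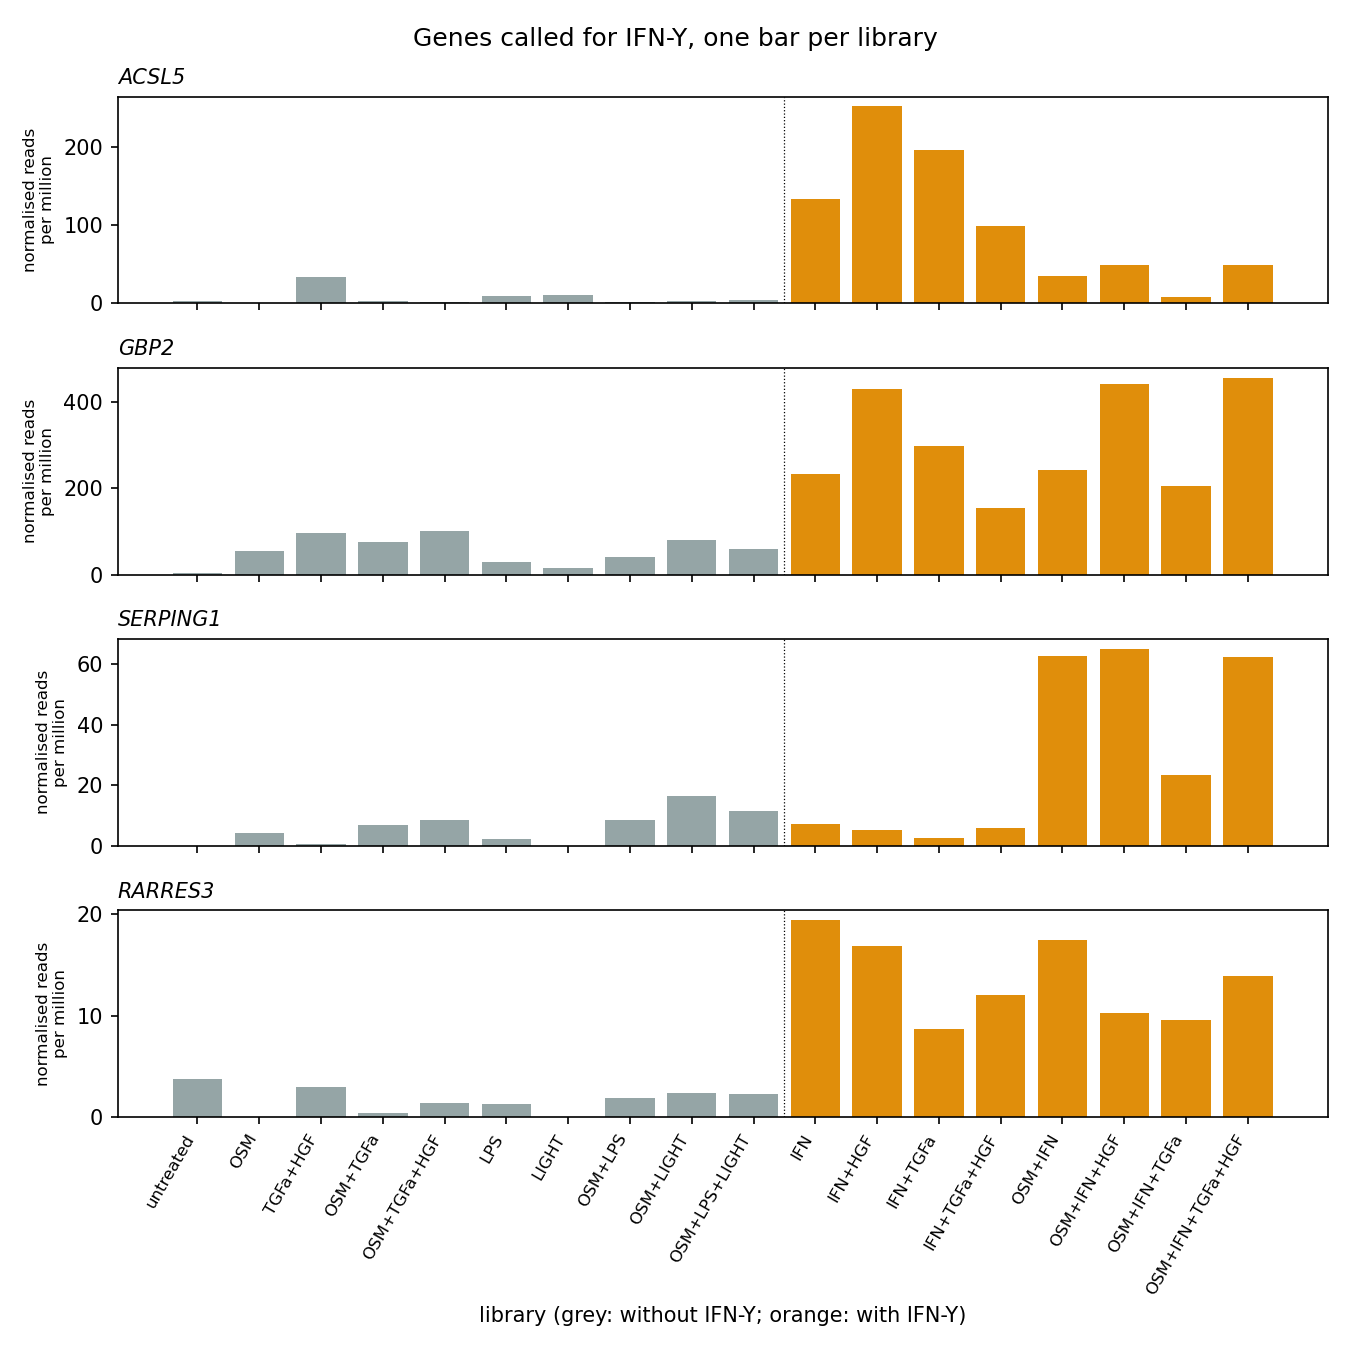
Normalised RPM of the 4 genes called for IFN-Y in each of the 18 libraries, with a bar per library, grey without and orange with IFN-Y. GBP2 was at 4.72 RPM in the untreated library and averaged 308 RPM over the 8 libraries with IFN-Y.

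These 4 genes were all that passed limma for IFN-Y, while 171 of 6278 had an unadjusted p under 0.05, and edgeR called 1, limma-voom 1 and DESeq2 15. ACSL5 kept its call in 35 of 36 alternatives, losing it in the fit with matched pairs as blocks, which called 0 genes. GBP2, SERPING1 and RARRES3 lost theirs on removal of any of 6, 14 and 14 single libraries, with limma adjusted p up to 0.168 without IFN+TGFa for GBP2 and 0.174 without OSM for the other pair.

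Interferon gamma target genes rose as a list. Of 15 measured members, 2 rose over all genes and 4 adjusted over the list alone, and 13 had positive fold changes, with a median log2 change of 0.71. PSME1, a proteasome activator subunit, was at 329 ± 79.2 RPM with IFN-Y (SD, n = 8) and 147 ± 61.0 RPM without it (SD, n = 10), and IFI30, a lysosomal thiol reductase, at 434 ± 140 RPM and 200.4 ± 88.0 RPM. The camera adjusted p was 1.10e-09, and adjusted p = 0.00930 with an estimated correlation. Of 14 genes typical of the type I interferon response, 0 passed limma over all genes and 2 rose adjusted over the list alone, OAS1 and IFI27, with a camera adjusted p of 4.99e-04 and adjusted p = 0.0316 with an estimated correlation. Of 13 STAT3 targets, 0 passed over all genes and 2 rose adjusted over the list alone, the complement proteases C1R and C1S, with a camera adjusted p of 0.0289 and adjusted p = 0.348 with an estimated correlation. That last call was lost on removal of any of 8 single libraries, with adjusted p up to 0.317 without the untreated library. PSMB10, an immunoproteasome subunit and 1 of 2 measured genes of MHC class I presentation, passed adjusted over the list alone, at 800 ± 485 RPM with IFN-Y and 290 ± 195 RPM without it. Most genes of MHC class I and II were too low in the counted window to be tested.

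For TGF-a, the question was whether an EGF receptor ligand moved genes in this background. Of 27 proliferation genes, 22 had negative fold changes, with a median log2 change of −0.27, and 0 passed limma, also adjusted over the list alone. The list passed camera (adjusted p = 0.0484) but not with an estimated correlation (adjusted p = 0.558), and the call was lost on removal of any of 11 single libraries, with adjusted p up to 0.214 without the untreated library. MKI67, a marker of cycling cells, was at 5.40 ± 3.28 RPM with TGF-a (SD, n = 7) and 7.44 ± 2.79 RPM without it (SD, n = 11). Of 9 MAP kinase output genes 0 passed limma, and the phosphatase DUSP6 was at 2.39 ± 3.74 RPM with TGF-a and 3.10 ± 4.86 RPM without it. All 22 members of that list have annotated 3' UTRs longer than the counted window, and together they had a median of 20.7 RPM. These values therefore do not show that MAP kinase output was unchanged. Over all genes, limma, edgeR and limma-voom called 0 genes for TGF-a and DESeq2 called 6, with 120 genes at an unadjusted p under 0.05 by limma.

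For HGF, 12 of 14 ATF4 targets had positive fold changes, with a median log2 change of 0.26, and 0 passed limma over all genes. The list passed camera (adjusted p = 0.0375) but not with an estimated correlation (adjusted p = 0.558). That call was lost on removal of any of 8 single libraries, with adjusted p up to 0.547 without OSM+TGFa+HGF. CTH, an enzyme of cysteine synthesis, was at 2.11 ± 1.09 RPM with HGF (SD, n = 6) and 0.232 ± 0.481 RPM without it (SD, n = 12), and was the 1 gene that passed adjusted over the list alone. Over all genes, limma, edgeR and limma-voom called 0 genes for HGF and DESeq2 called 5, with 136 genes at an unadjusted p under 0.05 by limma.

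For LPS, 23 of 29 ribosomal protein genes had positive fold changes, with a median log2 change of 1.16. The list passed camera (adjusted p = 8.32e-06) but not with an estimated correlation (adjusted p = 0.103) or without the untreated and LIGHT libraries (adjusted p = 0.0556), a subset chosen after seeing the data. RPL32 was at 7491 ± 648 RPM with LPS (SD, n = 3) and 3316 ± 1860 RPM without it (SD, n = 15), and RPS2 at 50155 ± 3508 RPM and 13799 ± 13740 RPM. None of the 29 passed limma over all genes or adjusted over the list alone, and the lowest adjusted p over the list alone was 0.0659 for RPL32. The libraries with LPS were also the deepest, with 9730655 (OSM+LPS), 11870640 (LPS) and 12596352 (OSM+LPS+LIGHT) window reads. The deepest library without LPS, OSM+IFN+HGF, had 9113742. An effect of LPS on lists or genes therefore cannot be told apart from depth here. The LPS and OSM+LPS libraries had the highest GC slopes of the 18, 0.47 and 0.49 log2 units per 10 GC points, and OSM+LPS+LIGHT had −0.01, while with the GC trend of each library removed the ribosomal list was still upward at a camera adjusted p of 1.51e-05. NF-kappa B targets, which LPS is known to induce in cells that respond to it, had 0 of 13 members past limma, also adjusted over the list alone, and RELB was at 45.2 ± 16.8 RPM with LPS and 32.5 ± 26.2 RPM without it. Of the 24 members of the full list, 21 have annotated 3' UTRs longer than the counted window. The simulated test for LPS recovered 28% of changes at a log2 size of 2, so a response is not excluded. TIMP2, a metalloprotease inhibitor, and S100A4 were higher adjusted over the list alone. Over all genes, limma, edgeR and limma-voom called 0 genes for LPS and DESeq2 called 84, of which 7 were higher and 77 lower, with 395 genes at an unadjusted p under 0.05 by limma. The median log2 change of all genes for LPS was −0.06 with the main scaling, −0.44 with library size only, −0.23 with upper quartile factors and −0.35 with DESeq2.

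For LIGHT, 3 lists passed camera, none with an estimated correlation. Ribosomal protein genes were higher, with a median log2 change of 0.70 over 29 members (adjusted p = 0.0167, and adjusted p = 0.558 with an estimated correlation). Proliferation genes were lower, with a median of −0.21 over 27 members (adjusted p = 0.00166, and adjusted p = 0.342 with an estimated correlation). Receptors of the added ligands were higher in 7 of 7 measured members (adjusted p = 0.0482, and adjusted p = 0.558 with an estimated correlation). No member of the 3 lists passed limma, also adjusted over the list alone. UBE2C, a mitotic ubiquitin-conjugating enzyme, was at 280.2 ± 93.1 RPM with LIGHT (SD, n = 3) and 510.3 ± 193 RPM without it (SD, n = 15). The camera calls were lost on removal of any of 5, 2 and 10 single libraries, with adjusted p up to 0.456 and 0.0927 without OSM+LIGHT and 0.553 without LIGHT. Over all 27 alternatives, single removals included, the ribosomal, proliferation and receptor lists were lost in 7, 5 and 17. The LIGHT library had 18.04 coding-span reads per 100 window reads, against 4.59 to 12.2 in the other libraries. Over all genes, limma, edgeR and limma-voom called 0 genes for LIGHT and DESeq2 called 8, with 136 genes at an unadjusted p under 0.05 by limma.

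Of the 13 receptor chains for the added ligands, CD14 was the most read, with a median of 76.6 RPM and a highest value of 592 RPM. EGFR had 272 reads over the 18 libraries, ERBB2 234, IFNGR2 183, IFNGR1 101, MET 83, OSMR 52, LTBR 48, TLR4 32 and IL6ST 23. LIFR, LY96 and TNFRSF14 had 0 reads. Of these, the annotated 3' UTR was longer than the counted window for all but CD14, ERBB2 and LY96, so the low reads do not show low expression for the others.

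Product terms asked whether the effect of an addition differed when another was present. None of 8 terms gave a gene past the limma threshold, with 22 to 770 genes at an unadjusted p under 0.05, the highest for OSM with LIGHT. That term rests on 1 library with LIGHT and without OSM, the LIGHT library, so the values given for it cannot be told apart from the state of that library. The smallest limma adjusted p was 0.0772 for COTL1, an actin-binding protein, in the OSM with LIGHT term, and 0.618 adjusted over the 8 terms together. Limma-voom and edgeR called 0, DESeq2 called 922 over the 8 terms, and upper quartile factors gave 241, all for OSM with LIGHT. The count was 0 without OSM+LIGHT or OSM+LPS+LIGHT and 85 to 499 without any other single library but LIGHT. Without LIGHT the OSM with LIGHT term could not be fitted, and the other 7 terms gave 0. Without LPS the OSM with LPS term could not be fitted.

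The position of 3' ends within the window was tested in 1063 genes. ST13, a co-chaperone of heat shock proteins, had a fitted shift of −42.4 nt with LIGHT (SE 6.35), with 3' ends at 334 ± 24.9 nt past the stop codon with LIGHT (SD, n = 3) and 366 ± 14.2 nt without it (SD, n = 15), with a limma adjusted p of 0.0279. It was the 1 gene called for any addition, and no gene was called for OSM, IFN-Y, TGF-a, HGF or LPS, with 86, 24, 14, 19 and 20 genes at an unadjusted p under 0.05 in limma. ST13 lost its call on removal of any of 12 single libraries, with limma adjusted p up to 0.261 without OSM+LPS+LIGHT, and the fitted shift of its median position was 0 nt. With median positions the 1 gene called was another, for OSM.

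Against the untreated library, each condition was described without a test, since no condition has a second library. The correlation of log2 levels with the untreated library over 6278 genes, which are not independent, ranged from 0.739 for IFN+HGF to 0.861 for OSM+LPS+LIGHT. The LIGHT library had 1109 genes at least 4-fold above the untreated library and 595 at least 4-fold below it, and OSM+LPS+LIGHT had 418 and 435. The untreated library had the fewest window reads and the lowest median correlation with the others, 0.804, against 0.821 (LIGHT) to 0.921 (OSM+LIGHT). The deepest libraries, OSM+LPS+LIGHT, LPS and OSM+LPS, had the highest correlations with it (0.861, 0.848 and 0.846). These values therefore do not measure how far each condition moved the cells. The first principal component held 30.5% of the variance between libraries, and its gene loadings followed GC content across genes (rho 0.64).

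**Figure D4:**
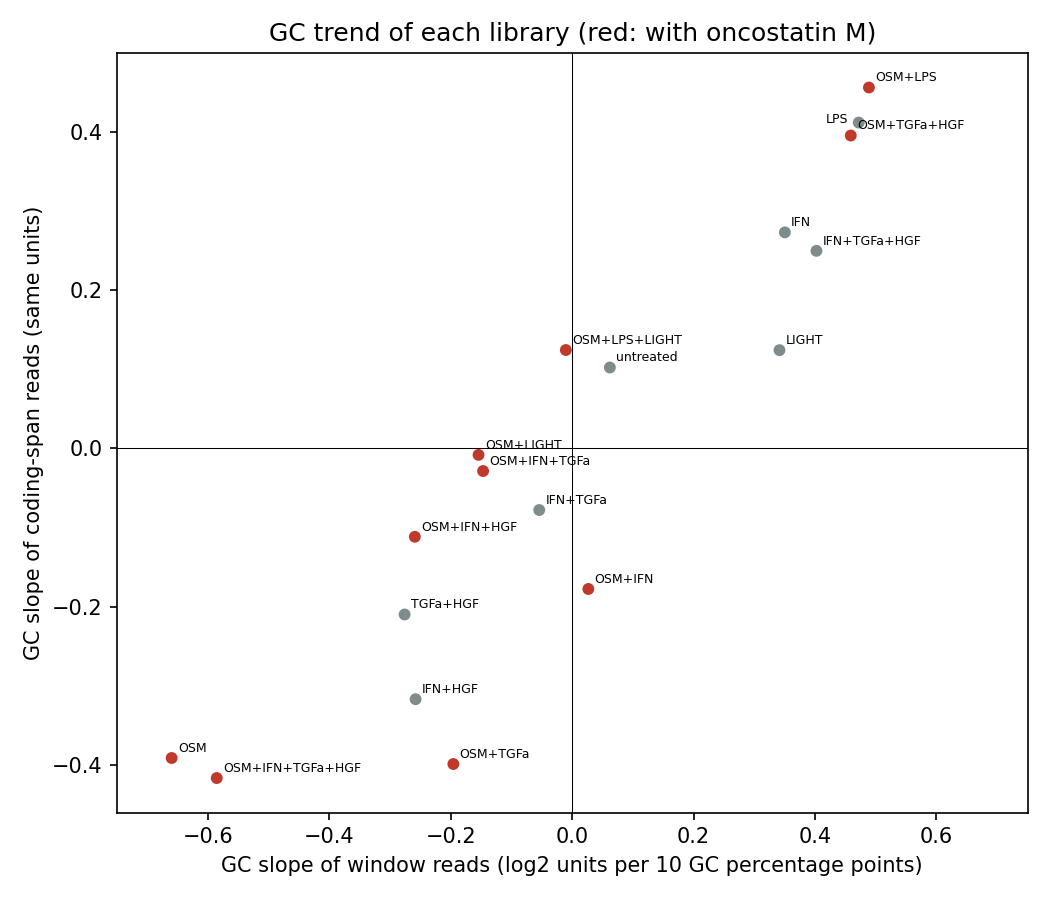
GC slope of window reads (horizontal axis) and of coding-span reads (vertical axis) in log2 units per 10 GC percentage points, a point per library, red with OSM. Window slopes run from −0.66 in the OSM library to 0.49 in the OSM+LPS library.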

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

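The tests of LIGHT in any combination and of library depth in this part were chosen after the result was seen, and the test of a few genes was not.

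The LIGHT library had 18.04 coding-span reads per 100 window reads and the IFN+HGF library had 12.2, against 9.92 in the untreated library, the control, and 4.59 to 8.88 in the other libraries. For each gene these are the reads of the transcript with the most coding-span reads, which need not be the one whose window was counted. Where that coding span holds the counted window of another transcript, window reads can be among them. Coding-span reads enter no comparison between groups except the alternative with window plus coding-span reads. The reads per 100 stood above the untreated level in both libraries. The LIGHT library was not matched by the others given LIGHT, which had at most 5.59, below the median of 7.37 in the libraries without LIGHT. Those libraries were deeper, with 8482257 (OSM+LIGHT) and 12596352 (OSM+LPS+LIGHT) window reads, and both also held OSM. Because coding-span reads per 100 fell with depth, their low values cannot decide on LIGHT in any combination as the cause. A few genes taking the coding-span reads is argued against, since the 10 top genes held 8.21% of them in the LIGHT library, 0.269 times the median of the other libraries. Library depth is argued against as the whole cause: the trend on log2 window reads in the 17 other libraries gave 9.27 per 100 at the depth of LIGHT, which lay 6.82 prediction errors above it, and the untreated library, with fewer window reads, had 9.92. A first test of depth, a count of shallower libraries with fewer coding-span reads per 100, found 1 and was undecided, and the trend replaced it with bounds set after the values were known. Over the 18 libraries, coding-span reads per 100 fell with log2 window reads (r = −0.694, permutation p = 0.00012, adjusted p = 2.40e-04 over 4 relations, and rho = −0.893, permutation p = 2e-05, adjusted p = 4e-05), and r was −0.695 without OSM+LPS+LIGHT and LPS, the pair farthest from the median depth. No other explanation was tested, so the source of these reads stays open.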

How the results depend on the processing

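In this part, edgeR on the recovered reads, both pseudocounts, coding-span reads, GC trend removal, the residual component, thinning, the fit without the untreated and LIGHT libraries and, for lists, library size only and single-library removal were chosen after the results were seen. None of the 12 list calls, nor the genes named with a call over all genes, reversed direction in the alternatives run for them, and genes named by the list-alone adjustment or without a call were not rerun. IL1RL1, IL1R2, TREM1, FGL1, S100A8, MTMR11, C11orf91, SERPINA1, MT1F, HSD17B2, KRT81, S100A4, SNCG, SERPINA3, CTSL and SERPING1 kept their calls for oncostatin M in all 36 alternatives, as did the interferon gamma and type I interferon lists for IFN-Y and the squamous list for oncostatin M in all 27.

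The cause of the following moves was not tested unless stated. For oncostatin M, where the main count was 217, DESeq2 called 604 genes, window plus coding-span reads 381, the residual component as a covariate 820 (330 higher, 490 lower), the fit without the 5 libraries that hold LPS or LIGHT 80 and the added product with IFN-Y 47, where the term becomes the effect without IFN-Y and rests on fewer libraries. Without the untreated and LIGHT libraries it called 135, of which 124 were shared. The other alternatives called 146 to 298, among them 173 with edgeR, of which 161 were shared, and 161 with thinned reads, of which 149 were shared. For IFN-Y, where the main count was 4, DESeq2 called 15 genes, and limma-voom, no filter, edgeR and the fit without LPS or LIGHT libraries 1 each, thinned reads 2 and matched pairs as blocks 0. DESeq2 called 6 genes for TGF-a, 5 for HGF, 84 for LPS (7 higher, 77 lower) and 8 for LIGHT. A term for the LPS or LIGHT libraries as a set gave 3 genes for LPS and 3 for LIGHT. The residual component gave 327 for LPS, all higher, whereas most LPS calls of DESeq2 were lower. That component was taken from the residuals of the same fit, so it left fold changes as in the main fit (median shift 0). It lowered only the error, so its 820 and 327 calls are no added evidence. Product terms gave 241 genes with upper quartile factors and 922 with DESeq2. Of the 12 list calls, an estimated correlation left 3 and fry gave 4.

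Removing each library in turn gave 135 (without LIGHT) to 546 (without OSM+TGFa+HGF) genes for oncostatin M, 1 to 4 for IFN-Y with 13 of the 18 removals giving 1 or 2, and 0 for TGF-a, HGF, LPS and LIGHT. The 5 removals that kept more than 2 genes for IFN-Y were untreated, IFN+HGF, LPS, LIGHT and OSM+LIGHT. List calls ranged from 6 (without OSM), with 7 without untreated, to 18 (without OSM+IFN+TGFa+HGF). Product terms ranged from 0 to 499 (without OSM+IFN), and were 0 without OSM+LIGHT or OSM+LPS+LIGHT. Without LIGHT the product of oncostatin M and LIGHT could not be fitted and the other 7 gave 0, and without LPS that of oncostatin M and LPS could not be fitted. The 3' end calls ranged from 0, in 11 removals, to 3 (without OSM+LPS), and ST13 was called without IFN, OSM+TGFa, OSM+IFN+HGF, OSM+IFN+TGFa+HGF, LPS or OSM+LPS. Without OSM+LIGHT the 1 call was for LPS. With median positions the count was also 1, but the gene was another, called for oncostatin M. No paired analysis by replicate number was possible because every library has the same number. With pairs matched by their additions as blocks, 146 genes were called for oncostatin M, of which 143 were shared. Depth limits low genes, since a read in the untreated library is 1 of 2279724.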

Other observations

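In this part, the GC test for oncostatin M, the window-edge test for longer 3' UTRs, and the tests of the first component against the 6 additions and against coding-span reads were chosen after the result was seen.

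Levels of some genes differed widely between single libraries, which have no replicate check. S100A9 was at 31670 RPM in OSM+LPS and 19322 RPM in OSM+TGFa+HGF, but at 458 RPM in OSM alone and 96.0 RPM in the untreated library. KRT81 was at 20844 RPM in the untreated library and at most 8681 RPM elsewhere, while KRT15 was at 2665 RPM in TGFa+HGF and 33.0 RPM in the untreated library. Glycolysis and hypoxia genes together held 183560 RPM in OSM+TGFa+HGF, where their median over libraries was 44238 RPM, and luminal markers held 39474 RPM in the untreated library, where their median was 11543 RPM. ACSL5 and SERPING1 passed for both cytokines. SERPING1 was higher with each, while ACSL5 was lower with oncostatin M and higher with IFN-Y, from 0.498 RPM in OSM to 252 RPM in IFN+HGF.

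The genes called for oncostatin M were weighed against technical explanations. Of 100 splits of the 18 libraries into groups of the same sizes, 1, the real one, called 217 genes or more. The highest other called 85, so as many calls were rare among these splits. In the other splits the real oncostatin M term was left out, so its effect entered the error and may have lowered their counts. Splits for IFN-Y, with groups of 8 and 10 libraries and oncostatin M kept in the model, reached 281 and 270. The count therefore does not exclude chance. The GC trend of the libraries is argued against as the whole cause, since 200 of the 217 genes (92.2%) were still called with it removed. Thinning reads to the smallest library kept 149 of the 217 calls, with a median ratio of fold changes of 0.993. Thinning leaves the expected RPM unchanged, so a ratio near 1 was likely whatever the cause, and depth stays undecided. Genes with annotated 3' UTRs of 400 nt or less, whose annotated ends lie inside the window, were called 2.10 times as often as the rest (122 of 2383). Longer genes can lose reads past the window, so this share may follow from reads alone. It cannot decide on a shift of 3' ends across the edge of the window. For the 95 called genes with longer 3' UTRs such a shift cannot be told apart from a change in level, because reads past the window were not counted. An effect of oncostatin M on transcript levels in the first group stays a hypothesis from the same data, which this share does not decide.

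The first component of the libraries followed GC content. The GC slopes of window reads and of coding-span reads, which do not overlap on the transcript, agreed over the 18 libraries (rho = 0.913, r = 0.922, permutation p = 1e-05 for both, the smallest that 100000 permutations give, adjusted p = 4e-05 over 4 relations, and r = 0.901 without OSM and OSM+IFN+TGFa+HGF). A GC-dependent step of library preparation is a candidate explanation, but both read sets come from the same genes, so a real change in GC-rich transcripts would give the same agreement. The 6 additions stay open, with an R squared of 0.459 (permutation p = 0.251), as does the share of coding-span reads (rho = −0.331, permutation p = 0.181, adjusted p = 0.242, and r = 0.0313, permutation p = 0.912).

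Splits of the libraries were also counted for the other results. For IFN-Y, 3 of 100 splits, the real one included, called 4 genes or more. That share is low, but the other 2 called 281 and 270, many times the real 4. Chance was therefore not excluded, and the count alone does not set IFN-Y apart. What those 2 splits share was not tested. For TGF-a, HGF, LPS and LIGHT, all 100 splits called as many genes as the 0 of the real split, and the highest others called 245, 3, 692 and 476. For gene lists chance was not excluded: 6 of 100 splits gave as many lists as the 3 for oncostatin M (highest other 4), 7 as the 3 for IFN-Y (highest other 4), 34 as the 1 for TGF-a (3), 40 as the 1 for HGF (3), 42 as the 1 for LPS (3) and 5 as the 3 for LIGHT (3). For the 3' end position with LIGHT, 6 of 100 splits called 1 gene or more and the highest other called 12, so chance was not excluded.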
